A study of Homo sapiens with 9 samples.

How the data were processed

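RNA was measured on 9 Affymetrix PrimeView arrays, each hybridised with RNA from a culture of MDA-MB231, an established human breast cancer cell line. Per the labels' protocols, cells were plated at 70% confluency and given fresh serum-containing medium with an inhibitor or vehicle on the following day. They were lysed 24 h later, and 4 cultures received 0.1% DMSO, 2 received 10 µM BB94 and 3 received 3 µM PD325901. BB94 is batimastat, a broad inhibitor of metalloproteinases, and PD325901 inhibits MEK, the kinase upstream of ERK. Both inhibitors were diluted from DMSO stock, and whether the DMSO content was levelled between the doses is not given in the sources used here. The labels call the samples biological replicates, and no batch or date was given in the sources used here.

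The deposited values are log2 probe set summaries that the authors made with RMA from the affy package, per the series design text. RMA corrects background, quantile-normalizes the arrays and summarises the probes of each probe set. The values were used as deposited, with no further scaling. The table held 49395 probe sets, of which 102 were Affymetrix control probe sets and were left out of the tests. The platform annotation paired 44988 probe sets with 1 gene symbol, 1832 with several and listed no gene for 2473. Of those with 1 symbol, 44961 matched a gene identifier in the RefSeq table of assembly GRCh38.p14, 0 symbols needed an update and 27 kept the annotation's own symbol. The RefSeq table was used for names only, and no coordinates are given, because the files name no genome build. Each gene was represented by its probe set with the highest mean over the 9 arrays, which gave 18132 genes, of which 11734 had more than 1 probe set. Where another probe set of a named gene was called in the opposite direction, this is stated.

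Array values carry no read depth, and the number of arrays per group limits the precision. Array medians over probe sets ran from 6.05 to 6.34 on the log2 scale. The 23 background probe sets had a median of 2.92 to 3.05 across arrays, and the highest of them lay between 6.02 and 6.50. The highest was taken as the background level. It is a strict floor near the array medians, so bounds can lie far below the fitted changes, and a gene under it need not be absent. A gene below that level on any array of its dimmer group has only a bound there, and where some arrays of that group lay above it their number is given. The change is given as "at least N-fold", from the brighter group's mean against the mean, per array, of the higher of the background level and the gene's own value. No fold is given where both groups lay below it or the bound was under 1, and the highest and lowest genes of the naming rule were taken by fitted change, so their order among bounds was not measured. RNA integrity was read from the difference between the 3' and 5' control probe sets of ACTB. It was 3.89, 3.75, 3.46 and 2.96 in control replicates 1 to 4, 3.91 and 4.22 in the BB94 replicates and 4.15, 3.61 and 3.50 in the PD325901 replicates. Every pair of arrays shared 387 to 1078 exactly equal values, and 0 pairs were equal throughout.

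Groups were compared with limma 3.58.1 in R 4.3.3, with lmFit and eBayes on log2 values, a coefficient per group and no covariate. The test is two-sided. All 9 arrays shared the estimate of spread, with 6 residual degrees of freedom. P-values were adjusted over all genes by the Benjamini-Hochberg method and a gene was called at an adjusted p under 0.05. Where an adjusted p is printed for a gene it comes from this limma fit. The pooled spread weighs on genes whose PD325901 arrays differ among themselves, because their BB94 comparison then carries the same error. Gene lists were compared with all other genes by limma's camera with a preset correlation of 0.01, adjusted over the 31 lists within a comparison, and again with a correlation estimated from the residuals. The lists held 675 distinct genes, of which 636 were measured. Counts of list members were taken over all genes tested and again adjusted over the list alone.

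The comparisons, lists, tests, alternatives and rule for named genes were fixed before the data were examined. For each inhibitor against control, the rule took the 6 highest and 6 lowest log2 fold changes among called genes whose treated arrays all lay beyond all 4 control arrays. It added up to 3 called members of each called list, chosen by absolute change, and 17 genes fixed in advance: AXL, MET, EGFR, ERBB2, ERBB3, MERTK, ADAM10, ADAM17, MMP1, MMP14, TIMP1, TIMP2, TIMP3, DUSP6, SPRY4, ETV5 and CCND1. For PD325901 against BB94 it took the 5 highest and 5 lowest. This gave 60 genes for PD325901, 40 for BB94 and 10 for their difference. Some list members outside the rule are named as well, and the text says that they were chosen after their values were seen.

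The alternatives fixed beforehand were the mean of a gene's probe sets, all probe sets without collapse, a filter at a mean log2 value of 5, eBayes with trend and robust settings, and a fit on the arrays of the groups compared. The others were array weights, centring each array on its median over genes, cyclic loess, the replicate number as a block, leaving out each array, an adjusted p under 0.01 and an absolute log2 fold change of at least 1. Added after seeing the data were fits with control replicates 1 and 2 or 3 and 4 alone, centring on the median over probe sets, and the ACTB difference as a covariate. Both inhibitors were compared with the same control arrays. The overlap of their calls was therefore set beside 100 simulations of unchanged groups, which kept the spread of each group. Each simulated array was a random mixture of the deviations of its group's own arrays, with no separate noise per gene. Genes therefore moved together along very few patterns, more rigidly than genes of real cultures would. The overlap was also set beside independent lists and 6 assignments of control pairs to the inhibitors.

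The fit was tested on simulated data with the real genes' control means and spreads, run on 18132 genes with 200 genes changed per inhibitor. For PD325901 against control it recovered 50.7% of genes changed by 0.5 on the log2 scale, and 100% of those changed by 1 or by 2. For BB94 against control it recovered 44.8%, 100% and 100% of the same sizes. For PD325901 against BB94 the shares were 42.1%, 98.5% and 100%. Among genes left unchanged, 18, 10 and 13 were called in these comparisons. A simulated shift of 0.5 in 1 list was called by camera at the preset correlation, with 0 of the other lists. The simulated genes varied independently of each other, so this does not test list calls where members are correlated. Limits on medians and slopes of tests chosen for patterns in the data are 95% percentile limits from 2000 bootstrap draws over genes, which do not cover differences between cultures.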

Results

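Gene expression was measured in MDA-MB231 breast cancer cells after 24 h with vehicle (n = 4), the metalloproteinase inhibitor BB94 (n = 2) or the MEK inhibitor PD325901 (n = 3). The series concerns the shedding of receptor tyrosine kinases from the cell surface by proteases and its part in resistance to kinase inhibitors. The comparisons therefore ask how far transcript levels changed when MEK or the proteases were inhibited. The first principal component held 73.3% of the variance between arrays and set the 3 PD325901 arrays, at 51.4 to 51.7, apart from the other 6, at -29.1 to -20.1. The second, with 10.2%, put control replicates 3 and 4, at -18.5 and -23.9, apart from replicates 1 and 2, which lay above 0. The BB94 arrays, at 5.33 and 7.95, lay on the side of control replicates 1 and 2. Both correlated with control replicate 2 at 0.9973, and that control with replicates 3 and 4 at 0.9971 and 0.9966. BB94 against all 4 controls therefore includes this division of the controls. The third component, with 6.54%, put the BB94 arrays, at 15.8 and 19.4, apart from the controls, at -17.8 to -4.90. The median SD over genes was 0.16 in the control group, 0.08 in the BB94 group and 0.09 in the PD325901 group on the log2 scale.

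PD325901 lowered the transcripts through which ERK signalling is usually read. Of 20 measured genes of ERK feedback and output, 18 fell and 2 were not called, and 18 fell adjusted over the list alone. SPRY4, an inhibitor of receptor tyrosine kinase signalling, went from 11.21 ± 0.09 (SD, n = 4) in control to 5.78 ± 0.97 (SD, n = 3), with 1 of the 3 treated arrays above background, a fall of at least 25.4-fold (adjusted p = 7.7e-07). DUSP6, a phosphatase of ERK, went from 13.36 ± 0.12 (SD, n = 4) to 9.35 ± 1.54 (SD, n = 3), a 16.2-fold fall (adjusted p = 1.5e-04). CCND1, which encodes cyclin D1, fell 9.78-fold, from 12.61 ± 0.15 (SD, n = 4) to 9.32 ± 0.27 (SD, n = 3; adjusted p = 3.6e-08). The transcription factor gene ETV5 had a log2 change of -4.35. ETV1, above background in 1 of 3 treated arrays, fell at least 23.9-fold, and ETV4, below background under PD325901, at least 9.53-fold. MYEOV, above background in 2 of 3 treated arrays, fell at least 31.8-fold (adjusted p = 9.8e-07) and MIG7 at least 8.95-fold. Of the 3 probe sets of SPRY4, 1 was called in the opposite direction.

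The fall in ERK output genes varied among the PD325901 arrays. DUSP6 stood at 11.04 in replicate 1 and at 8.99 and 8.02 in replicates 2 and 3, against 13.36 in control. SPRY4 stood at 6.72, 5.83 and 4.78 in the same order. The median change of the list from the control mean was -2.30 in replicate 1, -2.78 in replicate 2 and -2.65 in replicate 3. In the BB94 arrays the list median lay at -0.04 and -0.15, and limma called 0 of the 20 genes, with 2 at an unadjusted p under 0.05. The SE of the BB94 change was 0.60 for DUSP6 and 0.38 for SPRY4, because it carries the spread of the PD325901 arrays. For such genes the lack of a call is weak evidence of no change.

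**Figure D1:**
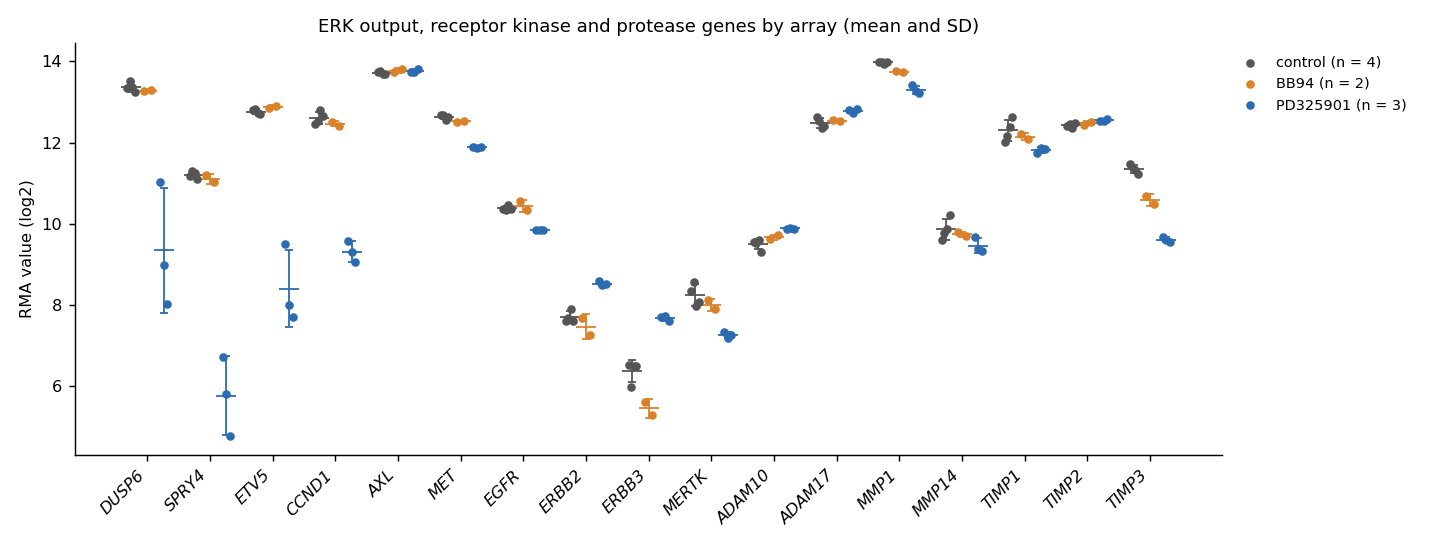
RMA values on the log2 scale (vertical axis) of the 17 genes fixed in advance, with 1 point per array and bars for the group mean and SD. The DUSP6 and SPRY4 points of PD325901 spread from 8.02 to 11.04 and from 4.78 to 6.72, while AXL lay at 13.71 in control and 13.77 under either inhibitor.

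Cell cycle genes fell as well. Of 41 measured genes of G1/S and DNA replication, 40 fell, with a median log2 change of -1.29. GINS2, a subunit of the replicative helicase complex, fell 4.97-fold (log2 -2.31, SE 0.09, adjusted p = 4.5e-08), CLSPN 4.63-fold and CDC45 4.42-fold. Of 35 G2/M and mitosis genes, 33 fell, with a median of -0.60, among them the mitotic kinase gene AURKB (log2 -1.40), ESPL1 (-1.13) and NDC80 (-1.02). Adjusted over the list alone, 40 and 33 were called as well. Of 26 genes of ribosome biogenesis and MYC targets, 15 fell and 11 were not called, and 17 fell adjusted over the list alone. DKC1, BOP1 and ODC1 led that list with -0.87, -0.80 and -0.73. Of 16 genes of arrest and quiescence, 12 rose and 2 fell, both counts the same adjusted over the list alone. The cyclin-dependent kinase inhibitor gene CDKN1C rose 4.23-fold (log2 2.08, SE 0.10, adjusted p = 1.2e-07), CCNG2 2.78-fold and TXNIP 2.21-fold. With camera the list adjusted p was 3.8e-18 for ERK output, 2.3e-34 for G1/S, 4.3e-20 for G2/M, 5.5e-08 for ribosome biogenesis and 0.011 for arrest. G1/S and G2/M kept their calls with an estimated correlation (adjusted p = 0.0316 for each). ERK output did not (adjusted p = 0.129 with an estimated correlation), nor did ribosome biogenesis (adjusted p = 0.108) or arrest (adjusted p = 0.192).

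Most genes of the epithelial and antigen presentation lists rose under PD325901, although neither list kept its call with an estimated correlation. Of 20 epithelial genes, 13 rose and 2 fell, over all genes and adjusted over the list alone. ELF3, an epithelial transcription factor gene, rose 12.2-fold, from 8.55 ± 0.10 (SD, n = 4) to 12.16 ± 0.04 (SD, n = 3; adjusted p = 3.2e-09). CDH3, which encodes P-cadherin, rose 6.29-fold, and the splicing factor gene ESRP1 was called with both groups below background. Luminal markers, with 4 of 12 higher and 3 lower, and mesenchymal genes, with 5 of 20 higher and 3 lower, were not called as lists (list adjusted p = 0.895 and 0.84). Of 18 antigen presentation genes, 12 rose and 1 fell, both also adjusted over the list alone. NLRC5, the transactivator of MHC class I genes, rose 9.55-fold (log2 3.26, SE 0.15, adjusted p = 1.2e-07), HLA-DMA 3.43-fold and HLA-DRA 2.75-fold. HLA probe sets can share signal between related genes. Of 31 interferon-stimulated genes, 16 rose and 3 fell, and 16 rose and 4 fell adjusted over the list alone. The chemokine gene CXCL10 rose at least 4.51-fold, MX2 at least 2.73-fold and CXCL11 at least 1.76-fold from control levels below background. The list adjusted p was 0.0086 for epithelial genes, 0.0021 for antigen presentation and 0.011 for interferon-stimulated genes. None of these 3 calls held with an estimated correlation (adjusted p = 0.269, 0.301 and 0.258). With control replicates 3 and 4 alone the epithelial and interferon lists lost their calls (adjusted p = 0.0647 and 0.081, within ranges of 2.0e-04 to 0.269 and 1.0e-03 to 0.258 over 22 alternatives).

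Cytokine genes moved in both directions. Of 21 inflammatory cytokine and NF-kB target genes, 12 fell and 6 rose, and 12 fell and 7 rose adjusted over the list alone. IL11 and IL1B fell at least 4.05-fold and at least 4.22-fold to levels below background, while the neutrophil chemokine gene CXCL5, above background in 1 of 3 treated arrays, rose at least 1.12-fold. Of 21 immediate-early genes, 6 fell and 3 rose, with IER2 at -1.05 and MCL1, which encodes an anti-apoptotic protein, at -0.94. EGR3, also called, was above background in 2 of 4 control arrays and in 0 of 3 treated ones. Of 22 genes of the integrated stress and unfolded protein response, 7 fell and 3 rose. The list lay lower (list adjusted p = 0.0193, and 0.162 with an estimated correlation), although its member with the largest change, DDIT4, an inhibitor of mTORC1, rose 13.9-fold (log2 3.79, SE 0.10, adjusted p = 3.2e-09). SDF2L1 had a log2 change of -1.11. XBP1, above background in 1 of 3 treated arrays, fell at least 1.42-fold and lost its call without PD325901 replicate 1 (adjusted p = 0.0531, range 6.4e-04 to 0.0531 over 20 alternatives). Of 8 endothelial markers, 3 fell. PECAM1, an adhesion molecule gene, went from 9.15 ± 0.05 (SD, n = 4) to 6.33 ± 0.46 (SD, n = 3), with 1 of 3 treated arrays above background, ESAM had a log2 change of -1.09, and KDR fell at least 1.18-fold. For the immediate-early, stress and endothelial lists the counts adjusted over the list alone were the same. The stress and endothelial lists lost their calls with control replicates 1 and 2 alone (adjusted p = 0.0628 and 0.0519, against highest values of 0.162 and 0.258 over 22 alternatives). The filter on the mean ended the stress (0.059) and immediate-early calls (0.0561), cyclic loess the stress call (0.05) and the mean of probe sets the endothelial call (0.0593). The list adjusted p was 0.0078 for inflammatory genes, 0.011 for immediate-early genes and 0.0193 for endothelial markers. With an estimated correlation none of these 3 held either (adjusted p = 0.276 inflammatory, 0.463 immediate-early, 0.258 endothelial).

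In total 6365 of 18132 genes were called in PD325901 against control, with 4142 higher and 2223 lower. At least 2-fold changes were called in 959 higher and 479 lower genes. DEFB1, which encodes a beta-defensin, rose at least 24.4-fold to 10.82 ± 0.06 (SD, n = 3), and MAF, a leucine zipper transcription factor gene, at least 16.1-fold. MB (myoglobin) rose at least 12.7-fold, CFB (complement factor B) at least 12.2-fold, SHOC1 at least 10.8-fold and CCN5, a matricellular protein gene, at least 8.97-fold. In all 6 of these, control lay below background. All 3 treated arrays lay above all 4 control arrays, which the naming rule itself required. The median log2 change of all genes was 0.08. Centring each array on its median over genes, which shifts all its genes alike, moved it to -0.17 and turned the split of calls to 2353 higher and 5076 lower, or 31.7% higher against 65.1%. Centring on the median over probe sets gave 3292 higher and 2964 lower. Under the first centring the lists that rose had medians of 0.34 for epithelial genes, 0.24 for antigen presentation, 0.18 for arrest and 0.12 for interferon-stimulated genes. Without centring, none of these 4 was called with an estimated correlation (camera adjusted p = 0.269, 0.301, 0.192 and 0.258), and the estimated correlation was not run on centred arrays. A shift alike for all genes tests a list against the others only weakly. The inflammatory, immediate-early, stress and endothelial lists lost their calls under this centring (adjusted p = 0.119, 0.0802, 0.0593 and 0.0512, against lowest values of 0.0032, 0.0028, 0.0072 and 0.0086 over 22 alternatives, and highest values equal to those with the estimated correlation).

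Receptor tyrosine kinase genes did not move as a group under PD325901. Of 42 measured, 13 rose, 8 fell and 21 were not called, the same adjusted over the list alone (list adjusted p = 0.831). AXL did not change detectably, at 13.77 ± 0.05 (SD, n = 3) against 13.71 ± 0.03 (SD, n = 4) in control, with a log2 change of 0.05 (95% interval -0.10 to 0.21, adjusted p = 0.625) that turned to -0.20 with arrays centred on their median. MET fell 1.67-fold (log2 -0.74, SE 0.07, adjusted p = 1.7e-05), EGFR 1.46-fold (adjusted p = 3.2e-04) and MERTK 1.97-fold (adjusted p = 2.4e-04). ERBB3, above background in 3 of 4 control arrays, rose at least 2.46-fold, from 6.38 ± 0.27 (SD, n = 4) to 7.69 ± 0.07 (SD, n = 3; adjusted p = 3.7e-05), and ERBB2 rose 1.77-fold (adjusted p = 2.5e-04). Of 28 receptor tyrosine kinase ligand genes, 9 rose and 10 fell (list adjusted p = 0.188), also adjusted over the list alone.

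Among the protease and inhibitor genes fixed in advance, TIMP3, a tissue inhibitor of metalloproteinases, fell most. It went from 11.35 ± 0.10 (SD, n = 4) to 9.61 ± 0.06 (SD, n = 3) under PD325901, a 3.33-fold fall (adjusted p = 1.9e-07). TIMP1 fell 1.39-fold (adjusted p = 0.0148), and TIMP2 had a log2 change of 0.12 (95% interval -0.04 to 0.28, adjusted p = 0.248), or -0.13 with arrays centred on their median. MMP1, a secreted collagenase, fell 1.60-fold (adjusted p = 4.8e-05). MMP14 had a log2 change of -0.40 (adjusted p = 0.0523). The sheddase genes ADAM10 and ADAM17 rose 1.31-fold and 1.23-fold (adjusted p = 0.0051 and 0.0179). Of 32 metalloproteinase genes, 8 rose, 9 fell and 15 were not called, and 9 rose and 10 fell adjusted over the list alone (list adjusted p = 0.0673). Of 16 inhibitors and sheddase regulators, 2 rose and 3 fell, the same adjusted over the list alone (list adjusted p = 0.467), RECK and PCSK6 higher and RHBDF1 beside TIMP1 and TIMP3 lower, with RECK, PCSK6 and RHBDF1 chosen after their values were seen. Centring on array medians ended the calls of ADAM10 (adjusted p = 0.302, range 5.2e-04 to 0.302) and ADAM17 (adjusted p = 0.72, range 0.0026 to 0.72). Leaving out PD325901 replicate 1 ended those of ADAM17 (adjusted p = 0.0619) and TIMP1 (adjusted p = 0.0632, range 6.2e-04 to 0.0632), leaving out replicate 3 that of ADAM17 (adjusted p = 0.0673). ADAM17 was also not called with centring over probe sets (0.112, log2 0.20), the replicate block (0.0564, log2 0.28) and control replicates 1 and 2 alone (0.066, log2 0.20). MMP14 was called without control replicate 1 or PD325901 replicate 1 (adjusted p = 0.014 and 0.0351, range 0.0028 to 0.201). It was also called with the filter on the mean (adjusted p = 0.0406), trend and robust settings (0.0369), array weights (0.012), either centring (0.0028 over genes and 0.0229 over probe sets), cyclic loess (0.0415) and control replicates 3 and 4 alone (0.0089).

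**Figure D2:**
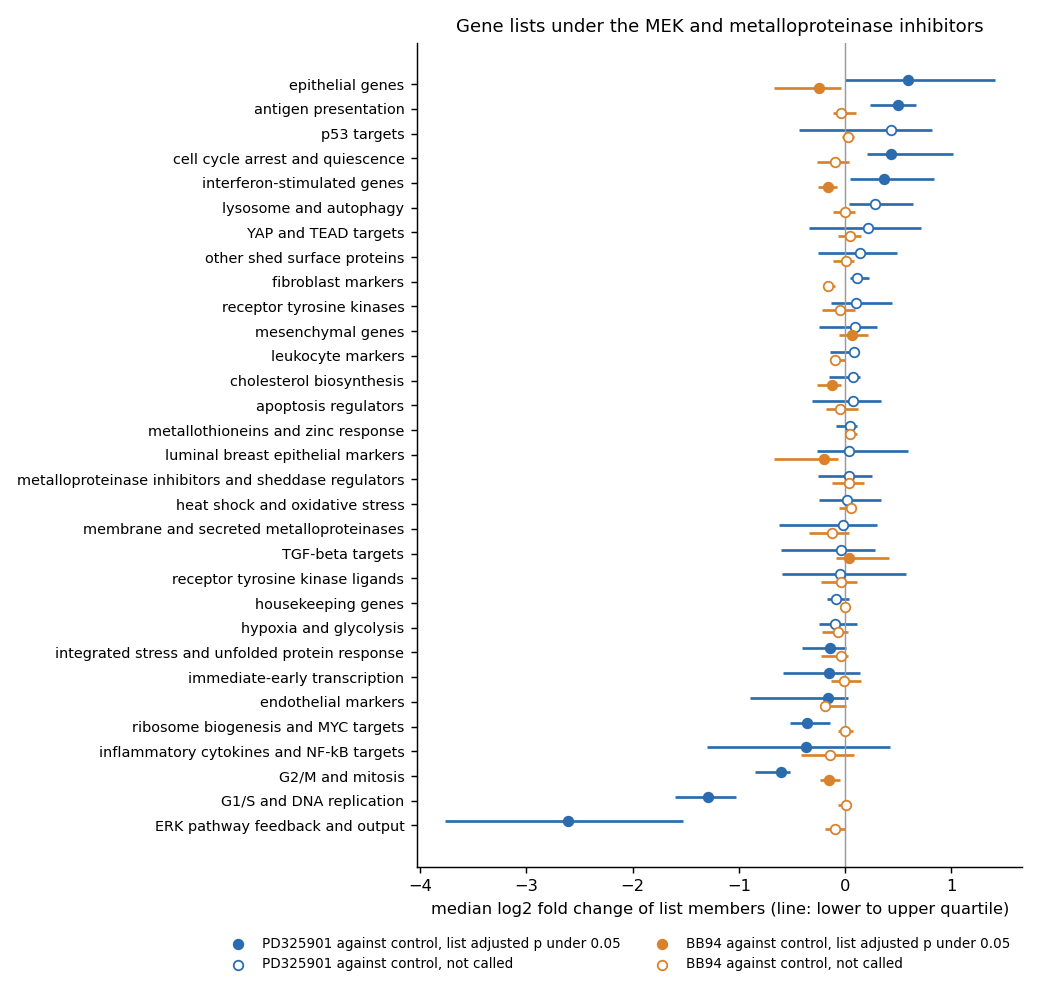
Median log2 fold change against control (horizontal axis) of the 31 gene lists (vertical axis), with lines from the lower to the upper quartile of members and filled points for lists with an adjusted p under 0.05 by camera at the preset correlation. ERK output genes lay at -2.61 under PD325901 and at -0.10 under BB94.

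BB94 changed far fewer genes, among them NNMT, SCNN1A and serum amyloid genes, which rose. NNMT, a methyltransferase of nicotinamide, went from 7.85 ± 0.07 (SD, n = 4) in control to 11.06 ± 0.01 (SD, n = 2), a 9.29-fold rise (log2 3.22, SE 0.09, adjusted p = 8.4e-08). SCNN1A, a subunit of the epithelial sodium channel, rose at least 3.05-fold from a control level below background, with 1 of its 2 probe sets in this direction. SAA1, an acute-phase protein gene, rose 5.70-fold to 13.52 ± 0.20 (SD, n = 2; adjusted p = 2.4e-06) and SAA2 at least 1.38-fold, and probe sets of these near-identical genes can share signal. TSC22D3, which encodes a leucine zipper protein induced by glucocorticoids, rose 4.56-fold (log2 2.19, SE 0.14, adjusted p = 5.6e-05), and the integrin gene ITGA10 rose 3.22-fold.

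KLHL28 and HES1 were among the genes that fell under BB94. KLHL28 fell at least 4.95-fold to a level below background, with 1 of its 2 probe sets in this direction. HES1, a transcriptional repressor downstream of Notch, went from 9.35 ± 0.52 (SD, n = 4) to 6.71 ± 0.11 (SD, n = 2), a 6.23-fold fall (log2 -2.64, SE 0.26, adjusted p = 7.9e-04). WNK3 fell at least 1.64-fold, ANXA10 at least 2.79-fold, the cystatin gene CST4 3.73-fold and the lymphotoxin gene LTB 3.65-fold. CST4 shares sequence with other cystatin genes. WNK3 lost its call without BB94 replicate 2 (adjusted p = 0.0544, range 6.7e-04 to 0.0544 over 20 alternatives).

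**Figure D3:**
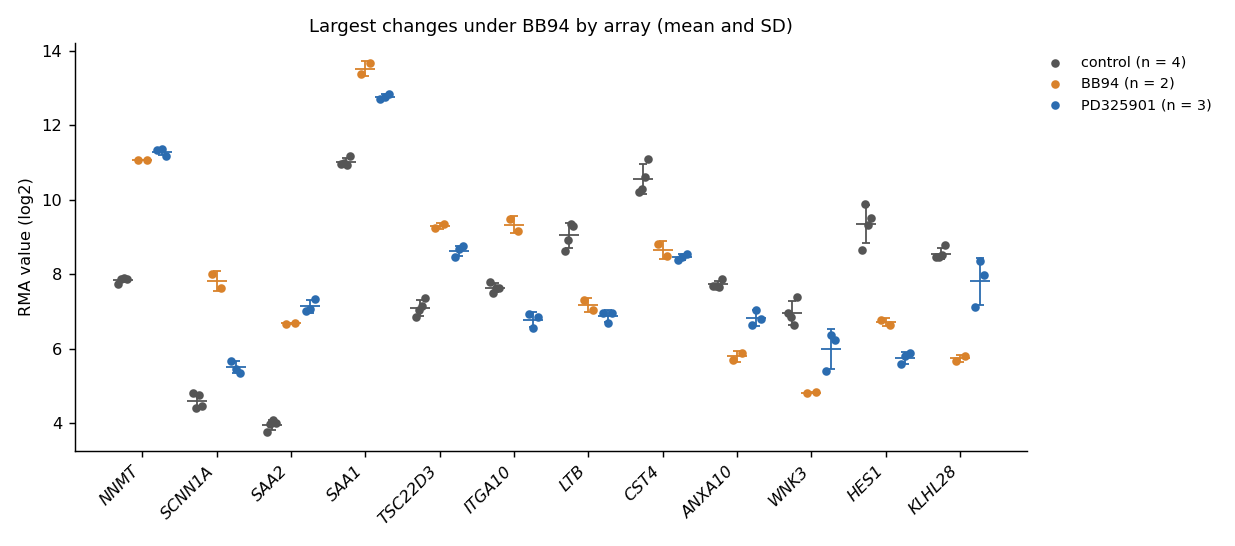
RMA values on the log2 scale (vertical axis) of the 6 genes with the highest and the 6 with the lowest change under BB94, with 1 point per array and bars for the group mean and SD. NNMT lay at 7.85 in control and 11.06 under BB94, and HES1 at 9.35 and 6.71.

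Some epithelial and luminal genes fell under BB94, and neither list kept its call with an estimated correlation. Of 20 epithelial genes, 6 fell and 14 were not called, and 8 fell adjusted over the list alone. ELF3 fell 2.61-fold (log2 -1.38, SE 0.11, adjusted p = 2.0e-04), and the claudin genes CLDN1 and CLDN4 had log2 changes of -0.93 and -0.77. Of 12 luminal markers, 3 fell, also adjusted over the list alone. AGR2 fell at least 1.96-fold, KRT19 had a log2 change of -0.67, and TFF1 was called with both groups below background. Of 31 interferon-stimulated genes, 2 fell and 5 fell adjusted over the list alone, with IFIT1 at -0.64 and CXCL10 below background in both groups. The list adjusted p was 7.4e-05 for epithelial and for interferon-stimulated genes and 0.0049 for luminal markers (adjusted p = 0.224 for each with an estimated correlation). Without BB94 replicate 2 the calls of CLDN1 (adjusted p = 0.0521), CLDN4 (0.163), KRT19 (0.238), IFIT1 (0.425) and CXCL10 (0.433) ended, each the highest value over its 20 alternatives. KRT19 also lost its call without BB94 replicate 1 or control replicate 3 (adjusted p = 0.164 and 0.0576), with the arrays of both groups alone (0.087, log2 -0.67), centring over genes (0.0522, log2 -0.59) or probe sets (0.0656, log2 -0.55), the replicate block (0.0937, log2 -0.55) and the ACTB covariate (0.0949, log2 -0.48). CLDN4 lost it with the block (0.0578, log2 -0.71) and the covariate (0.0567, log2 -0.70), with changes nearly as large as before. IFIT1 kept its call in 8 of 20 alternatives and CXCL10 in 5, and each lost it without control replicate 3 or 4 or without any of the 3 PD325901 arrays, IFIT1 also without control replicate 2 and CXCL10 without BB94 replicate 1 (adjusted p = 0.0574 and 0.148). Both also lost it with the arrays of both groups alone, the replicate block, the ACTB covariate, control replicates 1 and 2 alone and centring over probe sets, and CXCL10 with trend and robust settings, centring over genes and cyclic loess. The log2 change of IFIT1 in its 5 settings was -0.51 to -0.64. The luminal list lost its call when genes with a mean under 5 were left out (adjusted p = 0.107, range 2.9e-04 to 0.224).

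Smaller shifts were called in 4 further lists under BB94, none of which held with an estimated correlation. The G2/M list had a median log2 change of -0.15 (list adjusted p = 6.5e-04, and adjusted p = 0.551 with an estimated correlation) with 0 of 35 members called by limma under either adjustment and 9 at an unadjusted p under 0.05. It lost its call without BB94 replicate 2 (adjusted p = 0.0536), and its median was -0.07 there. Cholesterol biosynthesis genes had a median of -0.12 (list adjusted p = 0.0213, and 0.553 with an estimated correlation) with 0 of 19 called by limma and 5 at an unadjusted p under 0.05. That call ended without control replicate 3, control replicate 4 or BB94 replicate 2 (adjusted p = 0.116, 0.0822 and 0.127, range 0.0021 to 0.713 over 22 alternatives). It also ended with the ACTB covariate (0.713, median -0.0576), control replicates 1 and 2 alone (0.7, median -0.0706), the replicate block (0.296), array weights (0.0643) and the filter on the mean (0.0505). Of 20 mesenchymal genes, SNAI2, a transcriptional repressor gene, rose 2.18-fold, and 3 rose adjusted over the list alone (list adjusted p = 0.0213, and 0.617 with an estimated correlation). Of 14 TGF-beta targets, PMEPA1 and ID1 rose by 0.88 and 0.57 on the log2 scale, and 4 rose and 1 fell adjusted over the list alone (list adjusted p = 0.0213, and 0.647 with an estimated correlation). The mesenchymal call ended without control replicate 1 or BB94 replicate 1 (adjusted p = 0.0905 and 0.261) and the TGF-beta call without control replicate 4 or BB94 replicate 1 (adjusted p = 0.0672 and 0.118). The mesenchymal call ended too with control replicates 3 and 4 alone (0.21), and the TGF-beta call with control replicates 1 and 2 alone (0.0742) and the filter on the mean (0.0509). SNAI2 lost its call without control replicate 3, BB94 replicate 1 or 2, or PD325901 replicate 2 or 3 (adjusted p = 0.0596, 0.186, 0.25, 0.0511 and 0.0517). It was also lost with the arrays of both groups alone (0.101, log2 1.12), the replicate block (0.0775, log2 0.89) and the ACTB covariate (0.131, log2 0.81). ID1 lost its call without control replicate 2, BB94 replicate 1 or 2, or PD325901 replicate 2 (adjusted p = 0.0615, 0.22, 0.126 and 0.0521). The same 3 settings ended it as well (0.0808, 0.0573 and 0.058), although its log2 change there was 0.57, 0.60 and 0.62, no smaller than with all arrays.

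Of the 17 genes fixed in advance, TIMP3 and ERBB3 were called under BB94. TIMP3 fell 1.70-fold, from 11.35 ± 0.10 (SD, n = 4) to 10.59 ± 0.14 (SD, n = 2; adjusted p = 0.0038), and ERBB3 fell at least 1.10-fold to a level below background (log2 -0.92, adjusted p = 0.0193). TIMP3 lost its call without BB94 replicate 2 (adjusted p = 0.0874, the highest over 20 alternatives), and ERBB3 without control replicate 3, BB94 replicate 1 or BB94 replicate 2 (adjusted p = 0.0507, 0.0636 and 0.323, range 0.0031 to 0.323). ERBB3 was also not called with the arrays of both groups alone (0.0832, log2 -0.92), array weights (0.0509, log2 -0.69), the replicate block (0.0715, log2 -0.86), control replicates 1 and 2 alone (0.0848, log2 -0.80) and the ACTB covariate (0.119, log2 -0.83). AXL had a log2 change of 0.06 (95% interval -0.12 to 0.24, adjusted p = 0.911), MET of -0.11 (adjusted p = 0.753) and EGFR of 0.06 (adjusted p = 0.917). ADAM10 and ADAM17 had changes of 0.17 and 0.05 (adjusted p = 0.609 and 0.938). DUSP6 stood at 13.27 ± 0.02 (SD, n = 2) against 13.36 ± 0.12 (SD, n = 4). Of 42 receptor tyrosine kinase genes, 3 fell, namely ROR1, ERBB3 and FLT1, the last below background in both groups, and 5 fell adjusted over the list alone (list adjusted p = 0.255). Of 32 metalloproteinase genes, MMP3 and ADAMTS9 had log2 changes of -0.83 and 1.40, MMP10 and MMP16 fell at least 1.39-fold and at least 1.14-fold to levels below background, and 8 fell and 1 rose adjusted over the list alone (list adjusted p = 0.0745). FLT1, ROR1 and these 4 protease genes were chosen after their values were seen.

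In total 286 of 18132 genes were called in BB94 against control, 89 higher and 197 lower, with 28 and 42 of them changed at least 2-fold. The ACTB difference between 3' and 5' probe sets was 3.91 and 4.22 in the BB94 arrays and 2.96 to 3.89 in the controls, and with it as a covariate 156 genes were called. The count was 62 without BB94 replicate 2, with 35 higher and 27 lower, 116 without replicate 1, 140 with the control and BB94 arrays alone, 312 against control replicates 1 and 2 and 1633 against replicates 3 and 4. After cyclic loess 172 genes were called higher and 203 lower. Centring shifts all genes of an array alike and so moves the split by construction, to 125 higher and 151 lower over genes and 217 and 149 over probe sets.

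The direct comparison of the inhibitors used the same 3 PD325901 arrays as that with control, so likeness between the 2 is partly built in. CCN5, MAF, DEFB1 and MB, below background under BB94, were higher under PD325901 by at least 8.76-fold, 15.7-fold, 23.8-fold and 12.4-fold. ELF3, which rose under PD325901 and fell under BB94, was 31.9-fold higher under PD325901 (SE 0.11 on the log2 scale, adjusted p = 2.7e-09). SPRY4, MYEOV, ETV1 and MIG7 were lower under PD325901 by at least 23.7-fold, 32.4-fold, 20.1-fold and 13.2-fold, and ETV5 had a log2 change of -4.47. In this comparison 5652 genes were called, 3804 higher and 1848 lower under PD325901. Centring on the median over genes, a shift alike for all genes of an array, moved the median log2 change of all genes from 0.11 to -0.21 and turned the split to 1990 higher and 5025 lower, and centring on the median over probe sets to 2471 and 3523. Of 41 G1/S genes, 39 were lower, also adjusted over the list alone, and of all lists only this one kept its call with an estimated correlation (adjusted p = 0.0326). The epithelial list lay higher under PD325901 than under BB94, with 13 of 20 genes higher over all genes and 13 higher and 1 lower adjusted over the list alone (list adjusted p = 3.0e-04, and adjusted p = 0.167 with an estimated correlation). The interferon list did as well, with 16 of 31 higher and 1 lower, and 18 and 2 adjusted over the list alone (list adjusted p = 1.7e-04, and adjusted p = 0.116 with an estimated correlation).

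Of the 286 genes called under BB94, 233 were also called under PD325901, 126 in the same direction and 107 in the opposite one. NNMT rose in both, by 3.22 under BB94 and 3.44 under PD325901, and the 2 changes were not called different (log2 difference 0.23, adjusted p = 0.103). HES1 had a log2 change of -2.64 under BB94 and lay below background under PD325901, at least 1.22-fold below BB94 (adjusted p = 0.0228 for the difference). ELF3 had -1.38 under BB94 and 3.61 under PD325901. Of the 126, 66 also differed between the inhibitors. Independent lists of these sizes would share 44.5 genes in the same direction, 20.3 higher and 24.2 lower, against 47 and 79 observed, and 55.9 in opposite directions. Unchanged groups simulated against the same controls shared a median of 0 genes in the same direction, with a range of 0 to 1928 over 100 simulations, and 3 of the 100 shared 126 or more. Both groups were unchanged in these simulations, whereas 35.1% of genes were called under PD325901, so a low median was built in. How many genes an unchanged BB94 group would share with the real PD325901 calls was not simulated. The covariance of the log2 fold changes was 0.012, against a simulated median of 0.0052 (range -4.8e-04 to 0.0345), a difference of 0.0067, and 22 of 100 simulations gave as high a covariance. Their correlation was 0.101, against a simulated median of 0.498, and genes are not independent replicates. The simulated genes moved along very few shared patterns, so the simulated ranges and correlation are a rough reference only. With separate pairs of controls for the 2 inhibitors, the count in the same direction was 59 to 369 over 6 assignments, that in opposite directions 37 to 613 and the covariance -0.0088 to 0.0094. The assignment with 369 had the 613, and another had 142 against 162, so in 2 of the 6 the opposite directions prevailed. The count of 126 was 37 without BB94 replicate 2, 58 without BB94 replicate 1 and 915 against control replicates 3 and 4.

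**Figure D4:**
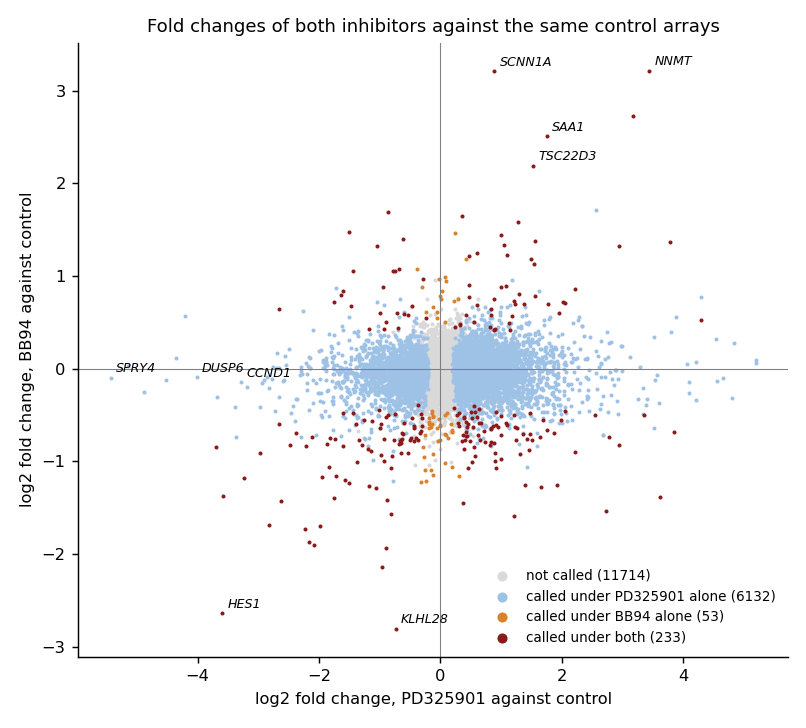
Log2 fold change of each gene under PD325901 (horizontal axis) and under BB94 (vertical axis), both against the same 4 control arrays, with 1 point per gene coloured by where it was called. The 233 genes called under both lie in all 4 quadrants, with NNMT at 3.44 and 3.22 and ELF3 at 3.61 and -1.38.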

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

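Control arrays that stood apart from the other 3 in a reported gene were looked for in 98 values. The gap to the nearest array, as a share of the range, passed the 95% critical value in 7 of them, against 4.9 that chance would give at 1 in 20. Control replicate 4 stood apart in MIG7 (0.938), ANXA10 (0.903), MAF (0.89) and ELF3 (0.848). MAF was 4.89 there and 5.55 to 5.63 in the other controls, ELF3 8.39 against 8.59 to 8.62, ANXA10 7.86 against 7.67 to 7.69 and MIG7 9.70 against 9.54 to 9.55. Control replicate 2 stood apart in ERBB3 (0.928), at 5.98 against 6.50 to 6.54, and in DKC1 (0.887), where the other controls lay at 10.78 to 10.80. Control replicate 3 stood apart in EGFR (0.832), at 10.48 against 10.35 to 10.37.

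Of all 49293 probe sets tested without collapse, 14480 were called in PD325901 against control and 737 in BB94 against control. Probe sets without a gene of their own were called as well, at lower shares. Of 1832 probe sets annotated to several genes, 468 were called in PD325901 against control and 23 in BB94 against control. Of 2473 with no gene listed, 604 and 26 were called. These probe sets were not used in the gene comparisons.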

How the results depend on the processing

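Of 2199 alternative values of named genes, 2101 kept direction and side of the threshold, 73 lost their call, 9 gained one and 16 changed sign. Of 660 alternative values of called gene lists, 586 kept both, 71 lost their call and 3 changed sign. The fits on control pairs, the probe set median and the ACTB covariate were chosen after seeing the data. The causes below were not tested unless the setting's own construction gives them, such as fewer arrays, more features or a stricter threshold.

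The count for PD325901 against control was 14480 with all probe sets and 1438 at an absolute log2 fold change of at least 1, and for PD325901 against BB94 12727 and 1557. For BB94 against control it was 737 with all probe sets, 70 at that fold change, 127 at an adjusted p under 0.01, 140 with the arrays of both groups alone, 469 with array weights, 1633 with control replicates 3 and 4 and 156 with the ACTB covariate. The overlap in the same direction was 305, 31, 62, 71, 194, 915 and 77 under these settings in the same order. Leaving out each array gave 5214 to 7446 genes for PD325901 against control, 62 to 367 for BB94 against control, 3800 to 6413 for PD325901 against BB94 and 37 to 171 for the overlap. Where this left a lone BB94 array, it was assumed to vary like the other groups.

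The deviations gave no clear sign that the shared replicate numbers pair the samples. For same-numbered control and PD325901 arrays they correlated at 0.05, -0.10 and -0.18. For control and BB94 arrays the values were -0.19 and 0.12, and for BB94 and PD325901 arrays 0.01 and 0.06. Deviations from means of so few arrays cannot exclude a pairing. With the replicate number as a block, 5950 genes were called for PD325901 against control, 161 for BB94 against control, 5756 between the inhibitors and 71 in the overlap.

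The changes of sign were in genes that were not called in the comparison concerned, and in 2 lists. Under BB94 with the replicate block, ETV5 was -0.088 and TIMP1 3.3e-03, and the TGF-beta list median was -1.9e-03. With the ACTB covariate ETV5 was -0.39, ADAM17 -0.0234, MMP14 0.0214, TIMP1 0.11 and the TGF-beta median -0.0354. With control replicates 1 and 2, ADAM17 was -0.0444, MMP14 0.0565 and TIMP1 0.0433. Leaving out each array gave -0.0427 (without BB94 replicate 1) to 0.166 for EGFR. With arrays centred on the probe set median, DUSP6 was 0.0235, SPRY4 0.0142 and MET 4.2e-03. With the mean of probe sets the median of the mesenchymal list was -0.0296. Under PD325901, centring on the median over genes gave AXL -0.20 and TIMP2 -0.13, and on the probe set median AXL -0.0475. For genes below the background probe sets, at 6.02 to 6.50 by array, the size of a change is limited to a bound.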

Other observations

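Other gene lists held called genes under PD325901 without a call of the list, where 35.1% of all genes were called, and the members named in these first 2 paragraphs were chosen after their values were seen. Of 28 ligand genes of receptor tyrosine kinases, EFNA1 (log2 1.54), PDGFD (1.02) and ANGPT1 (at least 3.21-fold, from below background) were among 9 that rose, and HBEGF (-2.04), EREG (-1.57) and NRG1 (-1.29) among 10 that fell. Of 14 TGF-beta targets, 3 rose and 5 fell (list adjusted p = 0.562), with the inhibitors of DNA binding ID1, ID2 and ID3 higher by 1.18, 2.08 and 2.62 and LTBP2 at -1.88. Of 22 lysosome and autophagy genes, 12 rose and 3 fell (list adjusted p = 0.0579), with the protease gene CTSD among those that rose. Of 16 apoptosis regulators, 4 rose and 4 fell (list adjusted p = 0.353), BCL2L11, which promotes apoptosis, at 0.93 and the protective genes BCL2A1, BCL2 and BCL2L1 at -2.39, -1.47 and -1.07. Of 17 p53 targets, 8 rose and 6 fell (list adjusted p = 0.907). Of 27 other shed surface proteins, 12 rose and 7 fell (list adjusted p = 0.722), and of 21 YAP and TEAD targets, 9 and 5 (0.639). Of 22 hypoxia and glycolysis genes, 3 rose and 7 fell (list adjusted p = 0.083), of 14 heat shock and oxidative stress genes 4 and 5 (0.733), and of 12 metallothionein and zinc genes 3 and 2 (0.907). Of 19 cholesterol genes 2 rose (list adjusted p = 0.728). Of 32 metalloproteinase genes, ADAMTS6 was among those that fell, at -2.59, with MMP10 and MMP3 lower by at least 1.23-fold and at least 2.42-fold, and MMP11 rose at least 1.38-fold. The fitted log2 changes of MMP10 and MMP3 were larger than these bounds, at -3.23 and -2.48.

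The lists of leukocyte, fibroblast and housekeeping genes were not called under PD325901. Of 11 leukocyte markers, 1 rose and 3 fell (list adjusted p = 0.639), the integrin gene ITGAM higher with both groups below background. Of 10 fibroblast markers, FBN1 rose by 0.63 and LUM rose with both groups below background (list adjusted p = 0.571). Of 13 housekeeping genes, HPRT1 and GUSB fell, at -0.44 and -0.34 (list adjusted p = 0.0673). Under BB94, limma called 0 genes of these 3 lists, with 0, 1 and 1 at an unadjusted p under 0.05, and their list adjusted p was 0.688, 0.255 and 0.419.

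The tests below concern patterns found in the same data. The tests of scaling were chosen after the array medians or the shares had been seen, and the others before their results were computed, the one with the ACTB covariate after its count of called genes had been seen. The real split of the 7 control and PD325901 arrays called 6365 genes, and 1 of 35 splits, the real one, called as many. No smaller share is possible with 35 splits, so the test argues against a chance division of the arrays but cannot exclude it. Nor does it address a difference between cultures that coincides with the groups. The highest other split called 2402 genes, and it kept the 3 PD325901 arrays together with control replicate 1.

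More genes were called higher than lower under PD325901, 65.1% of calls. Between-array scaling was not settled as the source. The share was 61.1% after cyclic loess (95% limits 59.9 to 62.3), and the limits reach below the bound of 60% set against scaling. Centring on the median over genes gave 31.7%, but it shifts all genes of an array alike and so sets the balance by construction, and decides nothing. Among genes above the median brightness the share was 58.2%, between the bounds set for and against a rise of dim probe sets as the source. Among the dimmer genes the share was 79.2%, and that part stays open. These tests did not settle what lay behind the balance of rises and falls, and no biological reading of it was tested.

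PD325901 replicate 1 lay above replicates 2 and 3 in 18 of 20 ERK output genes, by a median of 0.32 on the log2 scale. Control RNA mixed into that sample would add the same share of control to every gene that fell. The extra share of DUSP6 was 16.3% of control. In 60 other genes that fell by at least 2 on the log2 scale, the median extra share was 0.151 of that of DUSP6. Its quartiles were 0.0474 and 0.229, and the 95% limits of the median were 0.116 to 0.188. The median was 0.151 also in the 32 of these 60 genes whose level at the share of DUSP6 would clear background (95% limits 0.104 to 0.188). This argues against control RNA as the source of the excess of DUSP6, the only ERK gene used as the measure. A smaller share of control RNA, as a source of the smaller differences in other ERK genes, was not tested and stays open. The median difference over all genes was 0.0467, against 0.32 in the ERK genes, so no offset of that size common to all genes remained. Quantile normalization largely fixes this beforehand, so the value cannot decide on scaling. Over 6347 other called genes the slope was 0.984 (95% limits 0.978 to 0.99), a response nearly as large in them as a set. These genes were called with replicate 1 included, and both sides of the slope subtract the same control mean. Both draw the slope towards 1, so a weaker response was not excluded. RNA integrity was not tested as a source, and the ACTB difference was 4.15 in replicate 1 against 3.61 and 3.50 in replicates 2 and 3. A difference in ERK signalling of that culture, such as in the exposure to the inhibitor, may remain, and the labels name nothing that would test it.

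Several genes that rose under BB94, among them TSC22D3, PER1, KLF9, DDIT4, SCNN1A, SAA1 and NNMT, are known as glucocorticoid-responsive, which raised the hypothesis of a glucocorticoid-like response. In 25 further members of such a list, 4 of which also stand in the lists fixed earlier, the median change under BB94 was 0.29 and the camera p was 2.2e-15 (0.0056 with an estimated correlation), with 4 called higher and 0 lower. RGS2 rose by 0.97, IRS2 by 0.67 and FKBP5, a classical target of the glucocorticoid receptor, by 0.59, and ANGPTL4 was called with both groups below background. The 7 genes first seen were called higher under PD325901 as well, SCNN1A with both groups below background, so their rise was not particular to BB94. Of the 4 further called genes, FKBP5 and RGS2 fell under PD325901, at -0.59 and -0.29, and IRS2 and ANGPTL4 were not called. The median over all 32 members was 0.44, with 0.35 against control replicates 1 and 2 and 0.51 against replicates 3 and 4. The lower of these was 0.808 of the full value (95% limits 0.659 to 1.09), and with the ACTB covariate the median was 0.956 of it (95% limits 0.63 to 1.19). Both limits include ratios under the bound of 0.8 set beforehand, so neither a difference among the controls nor one in RNA integrity was excluded as part of the shift. A glucocorticoid-like response to BB94 may be considered beside them, and with 2 BB94 arrays a difference in the handling of these cultures cannot be excluded either.

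HES1 fell under BB94, which raised the hypothesis of lower transcription of Notch targets in general. In 14 other Notch target genes, 5 of which also stand in the lists fixed earlier, the median log2 change was -0.13 with a camera p of 0.171 (0.554 with an estimated correlation), and limma called 0, with 3 at an unadjusted p under 0.05. NRARP had a change of -0.44 (adjusted p = 0.162) and HEY1 of -0.30 (adjusted p = 0.128). HES1 was called lower under PD325901 as well, so its fall was not particular to BB94. Of the other members, HEY1, NRARP, NOTCH1, JAG1 and MYC were called lower under PD325901, and HEYL, NOTCH3 and GATA3 higher. The bound set beforehand on p cannot exclude a small shift, because the limits of the median (-0.22 to -0.02) lay below 0. The test did not show a shift of the list beyond that of other genes, and the question stays open.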
